A study of Escherichia coli with 4 samples.

How the data were processed

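The series measured which barcodes belong to which 3′UTR reporter plasmids. Per the labels' protocols, plasmid pools were amplified in E. coli, purified, and cut and tagged with Tn5, a transposase that fragments DNA and joins adapter sequence to the fragments in a single reaction. The fragments were then amplified by PCR and size selected on a gel. The labels name 4 libraries, which are a pilot pool and the plates A, B and C of a collection called UTRome. Each was treated as a group of its own with 1 library, so there was no replicate library. The submitters' processing notes name cutadapt, a tool that trims adapter sequence from reads, and Bowtie2, a short-read aligner. Their versions and roles, the sequences used for alignment, the read support required for a link and any filter on the links are not given in the sources used here.

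The authors deposited a single table of text for the whole series. Per the file header it has 2 columns, the position of a 3′UTR clone and a barcode. A position combines a plate number, a well and a gene name, and the plates numbered there are called clone plates here to keep them apart from plates A, B and C of the labels. Nothing in the table ties a line to a library, and it holds no read counts. The depth per library is therefore unknown, and values are given for the table as a whole. The planned comparison between libraries, the overlap between the pilot and UTRome pools, the reads per barcode and the minima of read support were not run for this reason. Gene names were used as deposited, including older symbols. The reference table used here covers E. coli genes of assembly ASM584v2, and 0 of the names in the deposited table equal a symbol in it. Upper and lower case were kept apart in this comparison. Letter case alone could give that count, so it does not decide whether names are shared. No genomic coordinates or 3′UTR sequences were used here, and the species of the 3′UTRs is not stated in the labels used.

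Each distinct position was taken as 1 3′UTR entry. The number of barcodes per entry was summarised by its mean, SD, median and quartiles, and the SD is a spread over 3′UTRs and not over libraries. Its variance divided by its mean was compared with 10000 simulated tables from a zero-truncated Poisson distribution of the same mean, which is the distribution expected when barcoded clones are drawn at random and entries without a barcode are not listed. Barcodes linked to more than 1 3′UTR were counted. Barcodes with a neighbour within 1 or 2 base changes were compared with 1000 simulated sets drawn from the observed base shares at each position, and pairs within a 3′UTR were compared with 1000 permutations of the 3′UTR names. Base shares have Wilson 95% intervals, and shares of 3′UTRs have exact binomial 95% intervals. These cover counting error only.

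The 6 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists with at least 5 members in the table were tested by a two-sided permutation test of the difference of means with 100000 resamples, or an exact test with under 10 members, and p-values were adjusted by the Benjamini-Hochberg method over the 4 lists tested. The lists were defined by gene symbols and by symbol prefixes, so a few members are of another kind than the list name, such as the kinase inhibitor CDKN1A among the protein kinases. They do not hold every gene of their kind, so the entries outside a list include further transcription factors, kinases and RNA-binding proteins. Intervals of differences are 95% bootstrap intervals from 10000 resamples. The named 3′UTRs are the 10 with the most and the 10 with the fewest barcodes, with ties broken alphabetically, and the 2 members of each list with the most and the 2 with the fewest. The comparison of clone plates was added after the data were seen.

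The tests were first tested on simulated data made from the barcode numbers of the 1404 entries. For a simulated list of 50 entries, the list test gave p under 0.05 in 6% of 100 tables without a shift, in 40% with a shift of 0.2 barcodes per 3′UTR and in 98% with a shift of 0.5. Lists of other sizes were not simulated in this way. These shares do not apply to the AU-rich list of 5 entries with its exact test. The test of the variance gave p under 0.05 in 4% of 50 Poisson tables, and 50 of 50 planted copies that differed by 1 base were found. Alternatives covered merged or excluded barcodes, 3′UTRs with few or many barcodes, joined gene names, a log2 scale, equal weights per 3′UTR and uniform bases in the random model. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.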

Results

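The plasmid sequencing linked 4245 barcodes to 1404 3′UTR reporter entries that carry 1388 gene names. A 3′UTR is the stretch of a messenger RNA after its coding region, and in the reporter collection each one is identified by the short barcodes on its plasmids. All barcodes were 12 bases long and held only A, C, G and T. The 4 libraries, a pilot pool and UTRome plates A, B and C with 1 library each, are not told apart in the table, and its read depth is unknown. The entries lay on 16 clone plates, of which 15 held 84 to 96 entries and plate 16 held 21. In total 351 of the 1404 entries (25%) belonged to at least 1 of the 6 gene lists. The transcription factor list was the largest of these with 252 entries, or 17.9% of the table, followed by the protein kinase list with 54 and the list of RNA-binding and RNA-decay proteins with 36. These are counts of the symbols and prefixes on each list and not of all such genes in the table. The list of AU-rich element and cytokine genes had 5 entries, that of cell cycle and apoptosis 4, and that of housekeeping genes 1.

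The first question was how many barcodes each 3′UTR had, since each barcode is a separate tag by which a reporter can be measured. The mean was 3.02 ± 0.754 barcodes per 3′UTR (SD over 1404 3′UTRs), and the median and both quartiles were 3. Exactly 3 barcodes were linked to 874 3′UTRs, or 62.3% (exact 95% interval 59.7 to 64.8%). There were 254 with 2 barcodes, 203 with 4, 45 with 5, 18 with 1 and 10 with 6. At least 3 barcodes were linked to 1132 3′UTRs, or 80.6%. The distribution was narrower than a zero-truncated Poisson distribution of the same mean, which gives 333 3′UTRs with 3 barcodes and 246 with 1. The variance was 0.188 times the mean, against 0.712 to 0.941 in 10000 simulated tables. The one-sided p was 0.0001, the smallest these simulations can give, and 0.0002 when doubled because the direction had not been set.

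**Figure D1:**
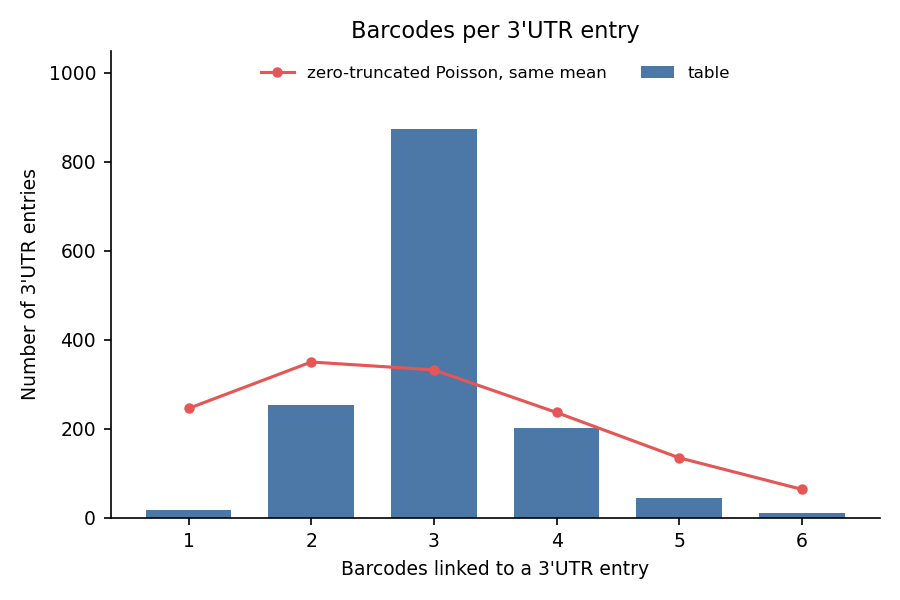
Number of 3′UTR entries (vertical axis) by the number of barcodes linked to them (horizontal axis), as bars for the deposited table and as a line for a zero-truncated Poisson distribution of the same mean. The bar at 3 barcodes reaches 874 entries, where the line is at 333.

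The 10 3′UTRs with 6 barcodes were those of CIC, CRSP7, E2F4, EN1, FOS, MAPKAPK5, NR4A2, PITX3, SAMD4B and ZNF182. CIC is a transcriptional repressor, E2F4 a cell cycle transcription factor, EN1 and PITX3 are homeobox factors, NR4A2 is an orphan nuclear receptor and ZNF182 is a zinc finger protein. FOS is the immediate-early gene of the AP-1 transcription factor, MAPKAPK5 a protein kinase downstream of MAP kinases, SAMD4B an RNA-binding protein of the Smaug family and CRSP7 an older symbol of a Mediator complex subunit. The barcodes of FOS, on clone plate 9, were ATCGCTGCTCTG, CTGTATTATGCC, ACGGAAAGTCTG, TATTGTGCTTTT, TACTGTTACGTG and TTTATGTCAGTC.

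A single barcode was linked to 18 3′UTRs, of which the first 10 in alphabetical order were ATF5, BRSK2, CDK2, CRSP2, DEC1, EN2, GTF2I, HSZFP36, KHDRBS1 and LMO1. ATF5 is a basic leucine zipper transcription factor, GTF2I a general transcription factor, KHDRBS1 an RNA-binding protein and BRSK2 a protein kinase. EN2, the paralogue of EN1, had 1 barcode where EN1 had 6. CRSP2, another Mediator subunit, had 1 where CRSP7 had 6, and the other CRSP entries, named after their values were seen, lay between them with 3 for CRSP3 and CRSP8 and 4 for CRSP6. CDK2, a kinase of the cell cycle, was linked only to GCATTCTCTCGT. Clone plates 14 and 15 held 5 of the 18, which were KHDRBS1 on plate 14 and CDK2, CRSP2, LMO1 and the receptor tyrosine kinase MET on plate 15. A 3′UTR with 1 barcode offers no second barcode against which its value can be compared.

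Gene lists were compared to ask whether 3′UTRs of some functional groups had more barcodes than others. Each list was compared with all entries not on it, and these include further genes of the same kind, such as the transcription factor E2F4, the protein kinase BRSK2 and the RNA-binding protein KHDRBS1. Among the AU-rich element and cytokine genes, FOS had 6 barcodes, ZFP36, which encodes an mRNA decay factor, had 5, MYC had 3 and JUN had 2. The remaining member was ZFP36L2 with 3, so no cytokine gene was among those compared. This list of 5 averaged 3.80 ± 1.64 barcodes (SD) against 3.02 ± 0.749 for all other 3′UTRs. The difference of 0.779 had a 95% bootstrap interval from -0.431 to 2.17. Its exact p of 0.04 became 0.16 after adjustment, so the difference did not pass.

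The 252 entries on the transcription factor list averaged 3.05 ± 0.729 barcodes against 3.02 ± 0.760 for entries not on it. Here 165 entries had 3 barcodes, 44 had 4 or more and 43 had 1 or 2. ZNF182 had 6 and ZNF334 had 5, while ZNF879 and TCF7, a transcription factor of Wnt signalling, had 1 each. The difference of 0.0294 (bootstrap interval -0.0692 to 0.132) did not pass, with an adjusted permutation p of 0.74.

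The 54 entries on the protein kinase list averaged 3.17 ± 0.885 barcodes against 3.02 ± 0.748 for entries not on it, a difference of 0.149 that did not pass (bootstrap interval -0.0852 to 0.390, adjusted permutation p of 0.33). MAPKAPK5 had 6 barcodes and CAMKK2, a kinase that activates other calmodulin-dependent kinases, had 5. CDK2 and MET had 1 each. The 36 entries on the RNA-binding and RNA-decay list averaged 2.97 ± 0.810 against 3.02 ± 0.753. The difference of -0.0526 (bootstrap interval -0.309 to 0.217) did not pass, with an adjusted permutation p of 0.74. ELAVL4, a neuronal protein that binds AU-rich elements, and RBM41 had 5 barcodes each, and the RNA helicase DDX43 and the translation initiation factor subunit EIF3S10 had 2 each.

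The cell cycle and apoptosis list had too few members for a test. BCL2L1, which encodes an inhibitor of apoptosis, and the cyclin CCND3 had 3 barcodes each, and the phosphatase CDC25A and the kinase inhibitor CDKN1A had 2 each. RPS3, a ribosomal protein, was the only housekeeping member and had 3. The list tests thus gave 0 differences past an adjusted p of 0.05 among 4 lists, and 1 at an unadjusted p under 0.05.

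There were 16 gene names with entries at 2 positions. Names were compared as deposited, so a gene entered under an older and a newer symbol is not counted here. Both entries had equal numbers of barcodes for 8 of them, including the transcriptional corepressor NCOR1 with 3 and 3. They differed by 1 for 6 names. The 2 names with a larger gap were chosen after their values were seen. They were ETV7, an ETS family transcription factor, with 5 and 2 barcodes, and TDRD10 with 4 and 2.

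Clone plates were compared after the data were seen. 3′UTRs on plates 14 and 15 had fewer barcodes than those elsewhere. Plate 14 averaged 2.46 ± 0.757 and plate 15 averaged 2.51 ± 0.929, each against all other entries with an adjusted permutation p of 8e-05 over 16 plates. A permutation test over all plates gave p of 5e-05, the smallest its 20000 resamples can give. These plates were joined because their means were the lowest, so a test of the pair adds nothing to those tests. Together the 190 3′UTRs of these plates averaged 2.48 ± 0.847 barcodes against 3.11 ± 0.703 for the other 1214. The difference was -0.624 (bootstrap interval -0.746 to -0.495, which does not allow for that choice). Of their 3′UTRs, 65.3% had 1 or 2 barcodes, against 12.2% elsewhere. The other 14 plates ranged from 2.91 on plate 10 to 3.24 on plate 13. Plates 7 and 13, with means of 3.23 and 3.24, passed against all other entries with an adjusted permutation p of 0.024 each, by 0.223 and 0.228 barcodes. Those other entries include plates 14 and 15, and without these the differences were 0.134 and 0.139 with an adjusted permutation p of 0.37 each and did not pass.

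**Figure D2:**
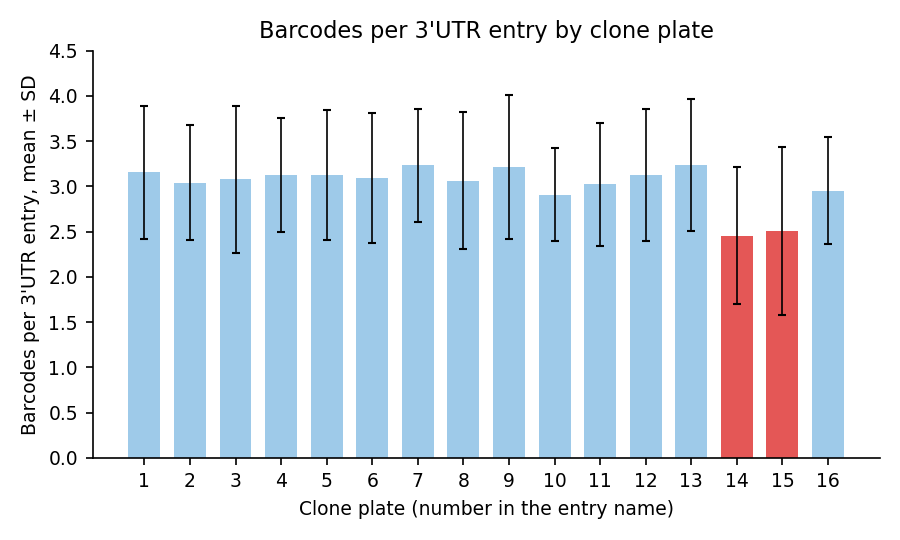
Mean number of barcodes per 3′UTR entry (vertical axis, bars, with SD over the entries of the plate as error bars) for each of the 16 clone plates (horizontal axis). Plates 14 and 15, drawn in red, average 2.46 and 2.51, and the other plates lie between 2.91 and 3.24.

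The next question was whether a barcode identified a single 3′UTR. Of the 4245 barcodes, 0 were linked to more than 1 3′UTR, which allows a share of up to 0.0707% by a limit of 3 counts and of up to 0.0869% by the exact 95% interval. Random barcodes of the same base shares gave a mean of 1.5 shared barcodes per simulated set, and 47.8% of 1000 sets had 0, so the absence of sharing did not differ from random draws. Whether shared barcodes were removed before deposit is not given in the sources used here. A count of 0 is the lowest possible and was common in the simulated sets, so this comparison cannot tell. Another barcode within 1 base was found for 51 barcodes (1.20%), against 1.27% in the simulated sets with a simulation p of 0.85. Within 2 bases there were 786 (18.5%), against 18.6% with a simulation p of 0.95. Of 26 pairs within 1 base and 444 within 2 bases, 0 belonged to the same 3′UTR, against means of 0.014 and 0.234 when names were permuted. Of 4555 pairs within 3 bases, 2 belonged to the same 3′UTR, against a mean of 2.38 with a one-sided permutation p of 0.69.

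The barcodes were compared with equal shares of the 4 bases. T was the commonest base at every position and made up 32.3% of all bases (Wilson interval 31.9 to 32.7%). A made up 23.5%, C 22.8% and G 21.5%. The share of T ranged from 29.8% at position 12 to 34.5% at position 3, counted from the first base listed, and that of G from 19.7% at position 3 to 22.9% at position 12. The mean GC content of a barcode was 44.2% ± 13.7 (SD over barcodes).

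**Figure D3:**
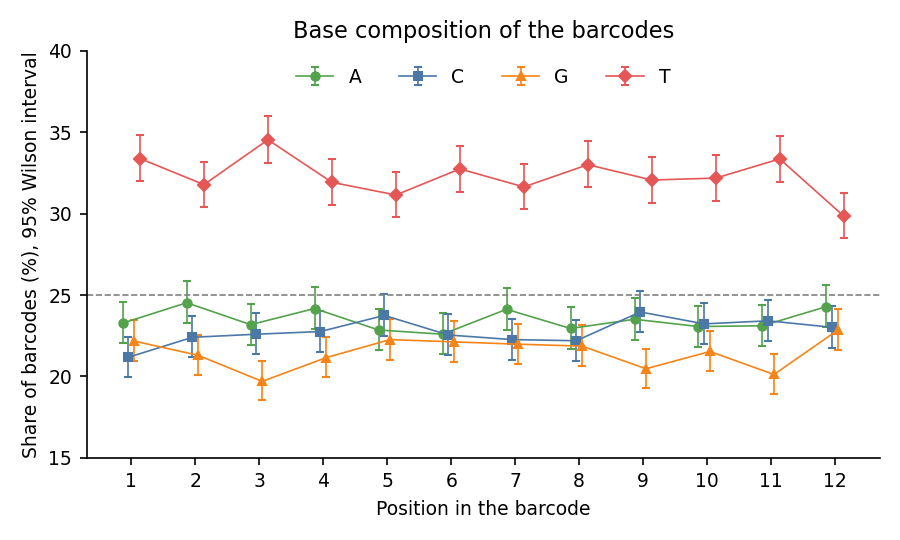
Share of each base in percent (vertical axis, points with Wilson 95% intervals) at each of the 12 barcode positions (horizontal axis), with a dashed line at 25%. T lies above the line at every position, between 29.8 and 34.5%.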

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

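The alternatives that leave out plates 14 and 15, permute list membership within plates, add the HNRP names to the RNA-binding list or drop members of another kind, and those of the plate difference, were chosen after seeing the data. Of 235 alternative values, 195 equalled the reported value, most of them because the setting left the result's entries as they were, and these are not counted as stable. Of the 40 that moved, 37 kept their side of the threshold, and their direction where a difference had passed it, or moved by less than the spread. Without plates 14 and 15, the differences of plates 7 and 13 from the others fell from 0.223 and 0.228 to 0.134 and 0.139, with an adjusted permutation p of 0.37 each, because the comparison group no longer held those low plates. The last exception was the share of barcodes with another within 2 bases. With uniform bases in the random model it was 1.25 times the simulated share with a simulation p of 0.002, against 0.994 times and p of 0.95 with the observed bases. Uniform bases ignore the excess of T, which raises the chance of close pairs by construction. Leaving out shared barcodes, merging barcodes within 1 base and keeping only barcodes of the commonest length changed 0 entries, so those 3 settings say nothing about stability. The same holds for joining gene names for the named 3′UTRs, and for joining names that share a plate for the plate difference. The mean of 3.02 barcodes per 3′UTR ranged from 3.002, without the 1% of 3′UTRs with the most barcodes, to 3.108, without plates 14 and 15, and the geometric mean was 2.93. The variance over the mean ranged from 0.159 to 0.219, and the share of T from 32.3 to 32.4%. The adjusted p-values of the gene lists ranged from 0.1 to 1 over their alternatives. The lower end was reached by the protein kinases and the AU-rich list without 3′UTRs of 1 barcode. The AU-rich list gave no value without the 1% of 3′UTRs with the most barcodes, since too few members were left. The plate difference of -0.624 was -0.36 on the log2 scale and kept its direction in each of the 3 alternatives that moved it. The minima of read support were not run, since the table holds no reads. No paired analysis was possible because each group has 1 library. The unknown depth limits what can be said of 3′UTRs with few barcodes.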

Other observations

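The comparisons of passes through the table, of inner barcode positions, of second barcodes between passes, of adjoining wells among the 8 3′UTRs named later, and of palindromes were tests chosen after the result was seen. The tests of gene content within lists, of T-rich barcodes, of close barcodes and of neighbouring wells without a barcode were written down before their values were computed, that of wells 2 away after the result for adjoining wells was known.

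Several gene families stood out among the names, some of them within the fixed lists. They were chosen after the names were seen and were not tested. Zinc finger genes with the prefix ZNF supplied 199 entries, or 14.2% of the table, with 3.08 ± 0.765 barcodes (SD). There were 25 HOX entries, which encode homeobox factors of body patterning, with 2.96 ± 0.539, 13 FOX entries with 3.15 ± 0.555 and 11 SOX entries with 3 ± 0.447. RNA processing was represented by 9 SNRP entries, which encode spliceosomal proteins, with 3.44 ± 0.527, by 10 HNRP entries with 3.10 ± 0.876 and by 7 LSM entries with 3.29 ± 0.756. The 8 entries of Mediator subunits with the prefix MED averaged 3.62 ± 0.518, with 0 at 1 or 2 barcodes and 0 on clone plates 14 and 15. Entries under the older prefix CRSP were not counted among them, and names were not matched between the 2 prefixes. The 13 entries with the prefix TAF, most of them subunits of general transcription complexes, averaged 2.62 ± 0.768, with 5 at 1 or 2 barcodes and 1 on those plates.

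The lines of the table ran through the 16 clone plates in 3 successive passes, with 1455, 1482 and 1301 barcodes, followed by 7 more, of which 5 lay on plate 14 and 2 on plate 15. These passes are a feature of the order of lines and are not assigned to the libraries of the labels. Of the 874 3′UTRs with 3 barcodes, 818 (93.6%) had 1 in each pass, against 19.2 to 24.6% when pass labels were permuted. The narrow distribution is consistent with about 1 barcode per 3′UTR from each pass, as a hypothesis.

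The shortfall of plates 14 and 15 lay in the third pass. There 20.0% of their 3′UTRs were listed, against 94.3% elsewhere, with means of 0.211 and 1.04 barcodes per 3′UTR, and with the 7 barcodes after that pass the mean of plates 14 and 15 was 0.247. Over the first and second pass their mean was higher, 2.24 against 2.07, a difference of 0.168 (bootstrap interval 0.0763 to 0.261) that lay in second barcodes: 14.2 and 16.8% of their 3′UTRs had 2 or more in these passes, against 7.74 and 8.65% elsewhere, while 94.7 and 97.4% were listed, against 94.9 and 95.1%. This argues against gene content that acts alike in every pass, while the difference within gene lists of -0.621 (interval -0.745 to -0.494) decides nothing, because no tested list differed in barcode number past its threshold. A loss of these plates at the step behind the third pass may account for the shortfall, but what that step was is open, and no biological explanation was tested.

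A subset of T-rich barcodes as the carrier of the excess of T is argued against. Such a subset would raise the variance of the number of T per barcode. That variance was 2.50, below the central range of 2.51 to 2.73 of simulated independent positions (two-sided simulation p of 0.04). Vector bases read into the barcode ends are argued against by a share of 32.4% (Wilson interval 31.9 to 32.9%) over the inner 8 positions. Multiplication of T-rich barcodes by sequencing errors was tested by the share of T among the 3459 barcodes without another within 2 bases. That share was 31.2% (30.7 to 31.6%), below the 32.3% of all barcodes. It decides nothing, since only 786 of the 4245 barcodes were left out. The share could reach 25% only if most bases of those 786 were T. Copies made by sequencing errors would be expected under the same 3′UTR as their source. Of 26 pairs within 1 base and 444 within 2 bases, 0 belonged to the same 3′UTR. Barcodes with another within 2 bases made up 18.5%, against 18.6% in the simulated sets. These values argue against such copies among barcodes within 2 bases of each other. An uneven base mix in the synthesis of the barcodes could give such an excess and was not tested, and no biological explanation was tested.

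Second barcodes in a pass recurred: PITX3, CIC, ZNF182, NR4A2, SAMD4B, E2F4, EN1 and FOS had 2 barcodes in each of the 3 passes, which makes 8, against a mean of 0.858 and a highest value of 6 in 10000 permutations within plate and pass (permutation p of 0.0001, the smallest they can give), so independent second barcodes are argued against. Mixing of neighbouring wells before the passes may contribute, but the test does not single it out. Of these 8, 2 pairs lay in adjoining wells (ZNF182 with NR4A2 and E2F4 with EN1), against a mean of 0.285 in random draws (permutation p of 0.023). That p was not adjusted, and anything else shared by adjoining wells would give such pairs too. Carry-over within a pass may also contribute, since 6.12% of wells next to one with a second barcode had none in that pass, against a mean of 5.01% (permuted range 4.24 to 5.76%, one-sided permutation p of 0.0015, 1 of 7 such shares computed), but without the third pass the share was 5.09% against 4.59% with p of 0.14. By pass it was 4.79% against 4.90% in the first, 5.35% against 4.31% in the second and 8.56% against 6.01% in the third (permutation p of 0.56, 0.058 and 0.0015), and of the 8 3′UTRs CIC had 3 blank neighbours summed over passes, PITX3 and ZNF182 2 each, FOS 1 and the others 0. For failure across regions of a plate, wells 2 away gave 4.68% against a mean of 5.00% (permuted range 4.41 to 5.61%, permutation p of 0.86), in the direction against it but within the range, and wells 3 away gave 5.43% against 5.09% (permutation p of 0.11), so it stays open, and no biological explanation was tested.

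The p-values of 16 palindromes of 4 bases and 64 palindromes of 6 bases were adjusted together. Among those of 4 bases the lowest adjusted one-sided Poisson p was 0.12, for CGCG in 64 barcodes against 88.0 simulated. Among those of 6 bases it was 0.12, for ACATGT in 1 barcode against 8.29 and GGATCC in 0 against 5.58. GGATCC was absent and still did not pass, so sites simulated at its level or lower could not pass alone. Simulated means of the 6-base sites ranged from 3.38 to 12.9, so the test cannot tell whether a 6-base site was depleted. Of 9 sequence motifs tested in the barcodes, including the polyadenylation signal AATAAA in 11 barcodes against 6.73 simulated, 0 passed, with a lowest adjusted p of 0.52.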
